A study of Homo sapiens with 9 samples.

How the data were processed

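Total RNA of 9 HUVEC cultures was labelled with biotin and hybridised to Affymetrix arrays, of type HuGene-2_0-st per the file headers. The labels name 3 groups of 3 cultures, static, ATPT flow and ATPT flow with DOX, and call the replicates biological. The authors deposited log2 expression values made with Affymetrix Expression Console and RMA, per the submitters' processing notes, with versions and settings not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes, so differences in overall signal between cultures are largely removed before deposit. The values have 2 decimals and were used as given. The authors' deposited table holds 1125 probe sets with their group averages (log2), the p-value of an F test over the 3 conditions, its FDR, and signed fold changes as a score, per the file headers. All of its rows have an FDR of at most 0.0999 and an absolute DOX fold of at least 1.5. Its averages lay within 0.021 of Tukey biweights of the values used here. A limma F test at an FDR under 0.1 with a biweight fold of at least 1.5 gave 1125 probe sets, of which 1118 are in that table.

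Of the table's probe sets 922 carry 1 symbol, 34 several and 169 none, and no gene was named from the last 2 kinds. Probe sets outside the table have no name here. Of the singly named probe sets 892 have a symbol or synonym in the RefSeq gene table of assembly GRCh38.p14, used for names only, since the array's annotation is of hg19 and no coordinates are given. XIST and Y-linked genes were left out.

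Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 48226 probe sets and all 9 arrays, so that the 3 groups shared one residual spread with 6 degrees of freedom. P values were adjusted by Benjamini-Hochberg, and a probe set counted as changed at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9. On simulated data for the DOX against flow comparison over 48226 probe sets, 76% of log2 changes of 1 and 95% of changes of 2 were recovered, with 7 false calls and 0 calls in a comparison without change. The simulation drew independent normal noise with the same spread in every group. It leaves out pairing, correlation between probe sets and a wider spread of the DOX arrays, so these shares may not hold for the real comparison.

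The replicate numbers of the labels were tested for pairing on deviations from group means. All 9 correlations between arrays of the same number in different groups lay between 0.17 and 0.483, and those between different numbers between -0.356 and 0.0208. Every pair exceeded 0.1, so the numbers were taken to pair the samples, and values with the replicate number as a block are given beside the results described where they change a call or move a count by over 1.5 times.

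Before the data were examined, 34 gene lists of 760 genes were written from general knowledge of endothelial flow and doxorubicin responses. Only 95 of these genes have a name here, 9 lists have no named member, and the 11 lists with at least 3 were tested with limma camera at a preset correlation of 0.01, against the 914 named genes. That background departs from the planned one of all genes and holds only genes chosen for a DOX response. Of the 922 singly named probe sets, 246 rose and 676 fell with DOX by the authors' fold. In DOX against flow a list that rose therefore stands out from this background more readily than a list that fell. Camera with an estimated correlation was run beside it, and so was fry, which tests a list without a background. Among the lists described below, named were 17 of 37 p53 targets, 12 of 35 G2 and M phase genes and 11 of 55 histones. So were 9 of 35 replication, 7 of 20 Notch and arterial and 6 of 24 flow-repressed genes. The endothelial identity list had 5 of 30, recombination 5 of 23, immediate early 5 of 23 and the flow-induced list 3 of 30. List medians and counts cover these named members only.

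Named genes followed a rule set before the data were examined. It takes 11 preset genes. It takes the 6 largest rises and 6 largest falls per comparison (4 and 4 for DOX against static) with an adjusted p under 0.05 and no overlap between replicates. It takes the called list members of largest change, and the 5 moved-back genes of each direction by the smaller of the 2 changes. RNA genes, antisense transcripts and uncharacterised loci were left out. One gene that the rule takes, and the result of a list that rests on it, are not reported here. The alternatives were the replicate block, only the groups compared, eBayes with trend and robust, quantile normalization, median centring, 2 filters on dim probe sets, array weights and leaving out each array.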

Results

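Human umbilical vein endothelial cells (HUVEC), primary cells from the vein of the umbilical cord, were profiled on 9 whole-transcript arrays. There were 3 static cultures without flow, 3 cultures under an atheroprotective shear stress waveform (ATPT flow) for 48 h, and 3 cultures under the same flow with doxorubicin (DOX) for 24 of the 48 h. Doxorubicin, an anthracycline that poisons topoisomerase II, was given at 250 ng/mL, or 431 nM. Each array gave log2 values for 48226 probe sets, and the median value per array lay between 4.63 and 4.79. Arrays correlated with r between 0.988 and 0.992 within the static and flow groups, and between 0.967 and 0.979 within the DOX group. The number of arrays, 3 per group, limits the precision of every value. Gene symbols were given for 922 probe sets of the authors' deposited table, which covers 914 genes. That table holds probe sets with a DOX fold change of at least 1.5, so a named gene was already chosen for its DOX response on these samples.

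The first comparison set flow against static culture and asked what the flow alone changed. ANGPT2, an antagonist of the TIE2 receptor, fell from 10.43 ± 0.89 to 5.72 ± 0.33 (mean log2 ± SD, n = 3), a log2 change of -4.71 (SE 0.55, limma adjusted p = 0.014). CNR1, the cannabinoid receptor 1, rose by 3.28 (SE 0.48, limma adjusted p = 0.03), and PTHLH, a parathyroid hormone-related peptide, rose by 3.21. CCDC68 rose by 3.16, the metalloprotease gene ADAMTS1 by 2.86 and the drug efflux transporter gene ABCG2 by 2.46. Beside ANGPT2, the largest falls among named genes that passed the test without overlap between replicates were those of the leukotriene receptor gene CYSLTR2 with -3.64, ABCA6 with -2.82, ACSM3 with -2.50, COLEC12 with -2.27 and the linker histone gene HIST1H1B with -2.21. A second ACSM3 probe set differed by -3.51, with a limma adjusted p of 0.0583 without the block and 0.0217 with it. In all, 242 probe sets changed with limma at an adjusted p under 0.05, of which 112 rose and 130 fell, and 160 changed at least 2-fold. Only 46 of the 242 had a symbol, 29 that rose and 17 that fell. With the replicate number as a block, 644 probe sets changed, 279 up and 365 down, and 235 probe sets were called in both fits. The count was 73, 122 and 57 without static replicates 1, 2 and 3, and 33, 74 and 52 without ATPT flow replicates 1, 2 and 3. Falls did not outnumber rises after median centring (96 up, 91 down), in only the 2 groups compared (139 up, 134 down), or without ATPT flow replicate 1 (19 up, 14 down), ATPT flow replicate 3 (28 up, 24 down) or static replicate 3 (30 up, 27 down).

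KLF2, a shear-responsive transcription factor, stood at 9.91 ± 0.61 in static culture and 11.71 ± 0.07 under flow (n = 3). Its log2 difference of 1.8 (SE 0.35) missed the threshold in the fit without block, with a limma adjusted p of 0.085, and passed it with the replicate block, with 0.0308. MKI67, a proliferation marker, differed by -2.12 (SE 0.42), with a limma adjusted p of 0.0847 without the block and 0.0345 with it. CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by -0.02 (limma adjusted p = 0.999). KLF2, CDKN1A and MKI67 were the 3 of the 11 preset genes that had a symbol here.

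The 12 named genes of the G2 and M phase list of the cell cycle, which holds 35, had a median log2 change of -1.55 under flow. Of these 12 genes 2 fell, NDC80 by a log2 change of -2.02 and TTK by -1.62, and 10 did not pass the test. With the replicate block 7 fell, and adjusted over the list alone all 12 fell. The list's shift gave a limma camera adjusted p of 6.64e-09, and the adjusted p was 0.474 with an estimated correlation. Of 9 named DNA replication genes 1 fell, RRM2, the small subunit of ribonucleotide reductase, with -1.80. With the replicate block 3 fell, and 5 fell adjusted over the list alone. That list had a camera adjusted p of 0.0124, and an adjusted p of 0.474 with an estimated correlation. Of 11 named replication-dependent histone genes 1 fell, HIST1H1B, and 2 fell with the replicate block. The camera adjusted p was 0.0476, and the adjusted p was 0.474 with an estimated correlation. That call also ended with the replicate block (0.0504), quantile normalization (0.0695), array weights (0.0647), only the 2 groups compared (0.0929), and without ATPT flow replicate 1 (0.053), static replicate 2 (0.0719) or static replicate 3 (0.0514).

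GCH1, named after its values were seen, which makes the nitric oxide synthase cofactor tetrahydrobiopterin, stood 2.18 higher under flow, with a limma adjusted p of 0.0725 that became 0.0163 with the replicate block. Of 7 named Notch and arterial genes JAG2, a Notch ligand, rose by 1.11 and C10orf10 fell by 1.70 on the log2 scale, and 2 rose and 1 fell with the replicate block. ANGPT2 was the 1 called member among 6 named genes of the flow-repressed list. The 3 named members of the flow-induced list, KLF2, SMAD6 and GJA4, did not pass the test, with log2 differences of 1.8, 1.26 and -0.43. The p53 target BTG2, the immediate early gene EGR1 and the Fanconi gene BRIP1, named after their flow values were seen, differed by -1.15, -1.89 and -1.46. Each missed the threshold without the block (limma adjusted p = 0.0509, 0.0831 and 0.174) and passed it with the replicate block (0.0306, 0.0405 and 0.0408). Of the 17 p53 targets 12 were lower and 5 higher under flow, with a median of -0.13. EGR1 was the 1 lower member of 5 immediate early genes, whose median was 0.17. All 5 Fanconi and recombination genes were lower, with a median of -0.30. Camera called none of the 3 lists, with adjusted p values of 0.347, 0.91 and 0.0653. The members of every list were read through a table chosen on these samples, so the lists are not independent evidence of their direction.

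The second comparison set flow with DOX against flow alone, the drug effect at constant flow. GJA4, the arterial gap junction protein connexin 37, fell from 9.69 ± 0.21 to 6.17 ± 0.34 (n = 3), a log2 change of -3.52 (SE 0.24, limma adjusted p = 0.00224). SOX18, an endothelial transcription factor, fell from 9.51 ± 0.19 to 7.22 ± 0.57, a change of -2.29. The other large falls among named genes that passed without overlap were those of the Notch coactivator gene MAML2 with -2.75, CDKAL1 with -2.50, the recombination gene RAD51D with -2.43 and SNX29 with -2.19. The largest rises among such genes were those of OMG with 3.90, the histone genes HIST1H2BG with 3.85 and HIST1H2AG with 2.45, the stress-induced transcription factor ATF3 with 3.01, the thymidylate synthase gene TYMS with 2.36 and EGR1 with 2.29. In all, 351 probe sets changed, 125 up and 226 down, of which 212 changed at least 2-fold and 247 had a symbol. With the replicate block 1063 changed, 350 up and 713 down, and 349 were called in both fits. The count was 8, 8 and 20 without ATPT flow replicates 1, 2 and 3, and 287, 3170 and 102 without DOX replicates 1, 2 and 3. Without DOX replicate 1, which had the lowest array weight (0.358), 160 rose and 127 fell, so falls no longer outnumbered rises. Fitted on the 6 arrays of these groups alone, 7 probe sets passed.

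**Figure D1:**
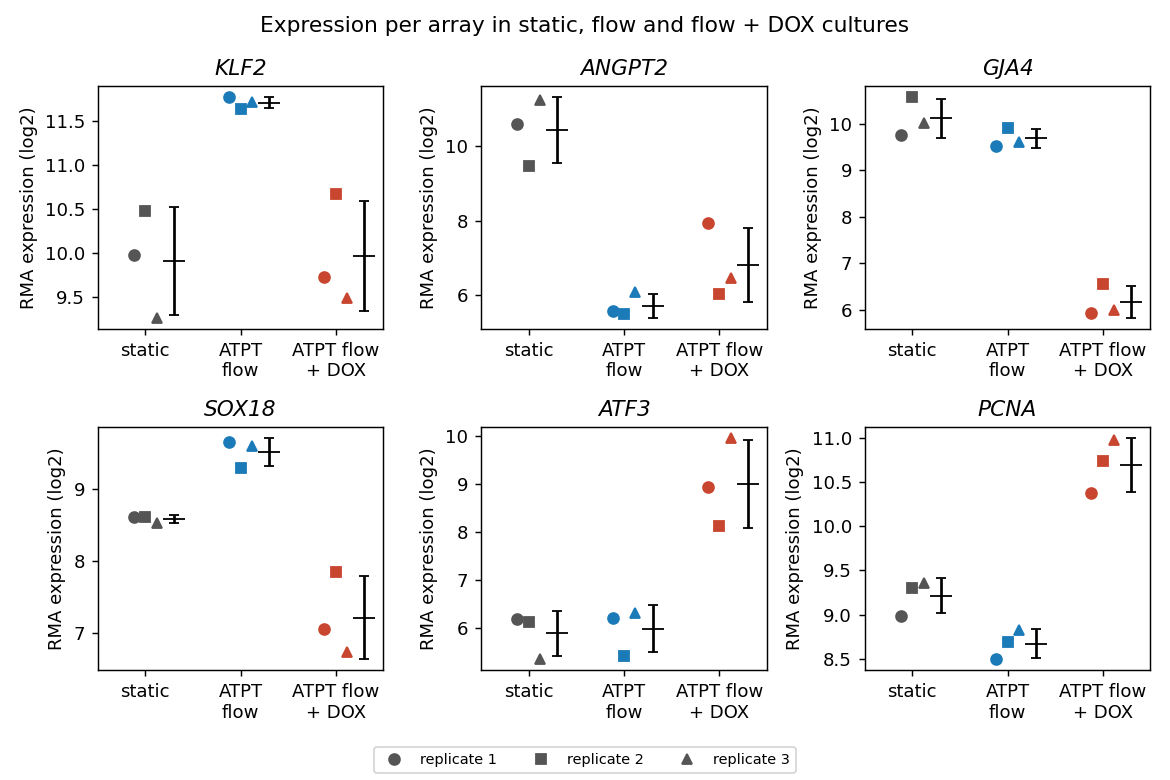
RMA log2 expression of 6 genes (vertical axis) in static, ATPT flow and ATPT flow with DOX cultures, with a symbol per array and the mean ± SD of 3 arrays beside it. For GJA4 the DOX arrays sit between 5.94 and 6.56 and the flow arrays between 9.52 and 9.92; for PCNA the DOX arrays sit between 10.37 and 10.97 and the flow arrays between 8.50 and 8.83.

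Of 17 named p53 target genes 9 rose with DOX and none fell. SESN1 rose by a log2 change of 1.87 (SE 0.24, limma adjusted p = 0.0217), TIGAR by 1.71, BTG2 by 1.54 and the death receptor gene TNFRSF10A by 1.53. With the replicate block 16 rose, and adjusted over the list alone 17 rose. Members of this and the other lists were named for a DOX fold of at least 1.5 on these arrays. Counts adjusted over a list alone largely follow from that choice and are not support for the list. The camera adjusted p was 2.72e-11, and the adjusted p was 0.171 with an estimated correlation. CDKN1A differed by 0.97 (SE 0.22), with a limma adjusted p of 0.101 without the block and 0.0527 with it. PMAIP1, a proapoptotic BCL2 family gene named after its values were seen, differed by 3.08, with a limma adjusted p of 0.105 that became 0.0287 with the block.

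Of 5 named immediate early genes 3 rose, ATF3 by 3.01, EGR1 by 2.29 and FOSB by 2.0, and 5 rose adjusted over the list alone. The camera adjusted p was 1.55e-04, and the adjusted p was 0.171 with an estimated correlation. Of 11 named histone genes 4 rose, HIST1H2BG, HIST1H2AG, HIST1H3H by 1.84 and HIST1H2BJ by 0.86. HIST1H1B, HIST1H2BM and HIST2H2AB differed by -0.63, -0.58 and -0.92 and did not pass the test. The histone list had a camera adjusted p of 1.26e-04, and an adjusted p of 0.171 with an estimated correlation. Histone genes are close copies of each other, and probe sets may share signal between them. HIST1H2BG stood at a mean of 3.21 under flow, below the lower quartile of the flow arrays (3.44). The authors' flow averages of HIST1H3H, HIST1H2BJ and HIST1H2AG were 3.51, 3.71 and 4.17, below the medians of the flow arrays (4.64 to 4.65). The sizes of these 4 rises are thus uncertain.

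DNA replication genes went both ways with DOX. PCNA, the replication clamp that p53 can induce, rose by 2.02 (SE 0.17, limma adjusted p = 0.00846) and TYMS by 2.36, and E2F8 and PRIM1 fell, with log2 changes of -2.06 and -1.33. The other 5 of the 9 did not pass the test, and with the replicate block 4 fell and 2 rose. Of 5 named homologous recombination and Fanconi genes BLM and BRCA1 fell, with log2 changes of -1.09 and -0.81, and 4 fell adjusted over the list alone. None of the 12 G2 and M phase genes passed the test without the block, and 5 fell with it. MKI67 differed by 0.02 (limma adjusted p = 0.993). The authors' averages of MKI67 were 7.58 under flow and 6.97 with DOX, a fold of -1.53. Its DOX value thus depends on how the 3 arrays of a group are averaged. Camera called none of these 3 lists, with adjusted p values of 0.844, 0.429 and 0.844, and the replication list had a median of -0.69 while camera gave it a positive sign. The named genes that camera set them against mostly fell with DOX. In fry the FDR was 0.178, 0.00627 and 0.092 for the replication, recombination and G2 and M phase lists.

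The 5 named genes of the endothelial identity list, which holds 30, had a median log2 change of -1.16 with DOX. The rest of the list has no name here and was not read. Of the 5 named genes SOX18 and ETS1 fell, ETS1 by 0.69 on the log2 scale, and with the replicate block 4 fell. Of 7 named Notch and arterial genes 3 fell, GJA4, C10orf10 with a log2 change of -1.90 and JAG2 with -1.03, and with the replicate block 5 fell and 1 rose. Of the flow-induced list GJA4 alone fell without the block, and all 3 named members fell with it. Camera called neither the endothelial identity nor the Notch list, with adjusted p values of 0.216 and 0.339, against named genes that mostly fell with DOX. In fry both lists had an FDR of 0.000714. Their members were chosen for a DOX change on these arrays, so the fry values are not independent evidence. KLF2 differed by -1.75 (SE 0.35), with a limma adjusted p of 0.0784 without the block and 0.0281 with it. The adrenomedullin receptor gene CALCRL fell by 1.25, and CTGF, a matricellular protein gene, fell by 1.08 on the log2 scale.

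**Figure D2:**
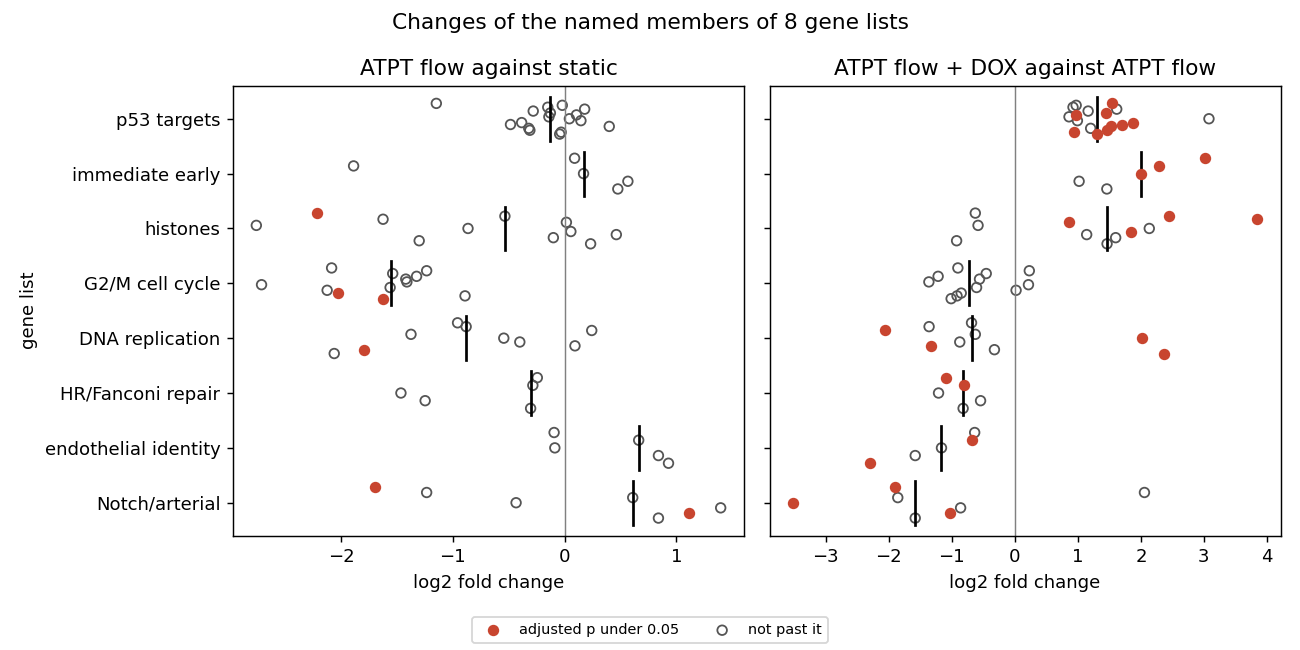
Log2 fold change (horizontal axis) of each named member of 8 gene lists (vertical axis), for ATPT flow against static and for ATPT flow with DOX against ATPT flow. Filled points passed a limma adjusted p of 0.05, open points did not, and black bars are list medians; the 17 p53 targets all lie above 0 with DOX, with a median of 1.30.

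The third comparison set flow with DOX against static culture. ATF3 rose by 3.10, CNR1 by 2.71 and KBTBD8 by 2.60, and the largest falls among named genes that passed without overlap were those of ACSM3 with a log2 change of -5.0, CYSLTR2 with -4.68, GJA4 with -3.95 and ANGPT2 with -3.61. ACSM3 had a second probe set, which fell by 3.32. KLF2 differed by 0.06 (limma adjusted p = 0.963), CDKN1A by 0.95 (0.0579; 0.0324 with the replicate block), and MKI67 fell by 2.10. Of the 12 G2 and M phase genes 11 fell, ASPM with -2.99, NDC80 with -2.87 and KIF11 with -2.77 among them, with a camera adjusted p of 0.00414 and an adjusted p of 0.69 with an estimated correlation. Of 17 p53 targets 9 rose, with 15 under the replicate block, a camera adjusted p of 1.89e-08 and an adjusted p of 0.391 with an estimated correlation. The immediate early list, with 4 of 5 members up, had a camera adjusted p of 0.00181, and an adjusted p of 0.391 with an estimated correlation. The histone list, with 5 up and 3 down, had a camera adjusted p of 0.00924, and an adjusted p of 0.463 with an estimated correlation. That call ended with both filters on dim probe sets, with 0.144 and 0.492, the second with a median log2 change of -0.48 against 1.5. All 5 homologous recombination genes fell. In all, 1436 probe sets changed, 580 up and 856 down, and 2956 with the replicate block, 1251 up and 1705 down. The count was 536, 520 and 511 without static replicates 1, 2 and 3, 1226, 3848 and 632 without DOX replicates 1, 2 and 3, and 301 when fitted on the 6 arrays alone. Without DOX replicate 1 676 rose and 550 fell, so falls no longer outnumbered rises.

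The last comparison asked which flow-regulated genes DOX moved back, that is, changed the opposite way to flow. No static culture received DOX, so these groups cannot show whether DOX opposed the flow response or acts alike without flow. Of the 112 probe sets that rose with flow 17 fell with DOX and 0 rose further in limma, against 0.525 and 0.29 expected from independent lists. Of the 130 that fell with flow 0 rose with DOX in limma and 3 fell further, against 0.337 and 0.609. With DOX 74 of the 112 were still called above static and 114 of the 130 still below it. The median DOX change was -0.33 for the 112, whose median flow change was 1.15, and 0.04 for the 130, whose median flow change was -1.36. FBXO36 rose by 1.72 with flow and fell by 1.75 with DOX, CAMK1D rose by 1.59 and fell by 2.05, and CMTM8 rose by 1.59 and fell by 1.62 on the log2 scale. SORBS2 rose by 1.20 and fell by 1.54, and ADGRE5 rose by 1.04 and fell by 1.58. With the replicate block 51 of the 279 that rose with flow fell with DOX and 2 rose further, and of the 365 that fell 16 rose with DOX and 16 fell further. Independent lists would give 4.13, 2.02, 2.65 and 5.4. The flow arrays enter both comparisons with opposite sign, which independent lists leave out. Unchanged groups simulated 100 times gave at most 0 moved-back probe sets, but a simulation without change makes almost no calls, so that count does not measure the effect of the shared arrays. The log2 changes correlated with r = -0.176 across probe sets, which are not independent replicates. The simulated r of -0.501 follows from sharing the flow arrays among unchanged groups of equal spread. It was fixed by the design, so the observed r cannot be judged against it. The covariance of the log2 changes was -0.0165, against -0.0186 simulated with the spread of the fit without block and -0.0123 with that of the blocked fit. Both spreads were pooled over the 3 groups, and DOX arrays varied more than flow arrays. Both simulated values may thus overstate the part of the shared arrays. Groups of 3 flow arrays cannot be split so that each part keeps 2, so part of the excess may come from the shared arrays. The count was 2, 2 and 3 without ATPT flow replicates 1, 2 and 3, 6, 7 and 5 without static replicates 1, 2 and 3, and 59 and 7 without DOX replicates 2 and 3.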

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

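Counts of changed probe sets depended on the arrays and the spread model more than on scaling, and the cause was not tested unless stated. Flow against static gave 242 probe sets, 644 with the replicate block, 386 with a log2 value of at least 6 in at least 3 arrays, 686 with array weights, and 33 to 122 with an array left out. DOX against flow gave 351, 1063 with the replicate block, 598 with that filter, 877 with array weights, 7 in only the 2 groups compared, and 8 to 3170 with an array left out. DOX against static gave 1436, 2956 with the replicate block, 301 in only the 2 groups compared, and 511 to 3848 with an array left out. Moved-back probe sets numbered 17, 67 with the replicate block, 26 after quantile normalization, 31 with the filter at 6, 55 with array weights, 2 in only the 2 groups compared, 9 at 2-fold or more in both comparisons, and 2 to 59 with an array left out. Filters test fewer probe sets, 14850 and 24112 of 48226, and the 2-group fits and left-out arrays use fewer samples. Fewer samples alone do not account for the low DOX counts of the 2-group fits. Flow against static, also fitted on 6 arrays, gave 273 there. Arrays of the DOX group correlated with r from 0.967 to 0.979, those within the static and flow groups from 0.988 to 0.992. With the spread of their own 6 arrays the DOX comparisons gave 7 and 301 probe sets, against 351 and 1436 with the shared spread. The shared spread was thus probably too small for the DOX comparisons, and their adjusted p values may be too low. The spreads themselves were not compared. Every probe set, named or not, is the reported analysis, so that alternative is identical. Of the called probe sets 30 of 242, 7 of 351 and 344 of 1436 were called in each of the 6 fits without 1 array of the compared groups, and all 242, 351 and 1436 kept their sign there.

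Camera called 4, 3 and 4 lists in flow against static, DOX against flow and DOX against static. With an estimated correlation it called 0, 0 and 0, and fry called 4, 8 and 10. For flow against static it called 2 with array weights and 2 in only the 2 groups compared. With an array left out the lists called ranged from 3 to 5, from 3 to 3 and from 4 to 4. The replicate block ended the call of 1 list, the histones under flow, and changed no other list call. In DOX against static the flow-repressed list, with a median of -0.19, was lower in fry (FDR 0.0321), and camera gave it a positive sign without calling it (adjusted p = 0.535). Of 4704 values of 113 genes under alternatives, 65 that passed no threshold changed sign. Arrays give no counts, so depth is not a limit here, but dim probe sets near background have compressed changes.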

Other observations

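Of the tests in this part, those on DOX replicate 2 and on the simulated covariance were chosen after the results were seen. The splits of the arrays and the covariance between pairs without a shared array were set before their results were seen.

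Several lists had too few named members to be tested, and those of their members not described above are given here. EPHX1, an epoxide hydrolase and NRF2 target, rose with DOX by a log2 change of 0.77 (limma adjusted p = 0.0427), and GPX1, a glutathione peroxidase, rose by 1.26 (0.0344). ZEB1, a transcription factor of mesenchymal transition, fell by 1.16, and NRF1, a regulator of mitochondrial genes, fell by 0.80 on the log2 scale with DOX. BOK, a BCL2 family gene, fell by 0.87 on the log2 scale with flow and differed by -0.50 with DOX (0.148). CFLAR, a caspase 8 inhibitor gene, differed by 1.8 with DOX (0.155) and by 0.39 with flow (0.985). IL6 differed by 1.34 (limma adjusted p = 0.101), HSPH1 by 0.80 (0.113), RPL7 by 0.73 (0.113) and PPP1R15A by 0.51 (0.304) with DOX and did not pass the test with or without the replicate block. CMPK2 differed by 0.71 (limma adjusted p = 0.0677, and 0.0418 with the block), TFPI2 by 1.05 (0.326 and 0.0448), RBMS3 by -1.56 (0.0587 and 0.0181) and ABCG2 by -1.04 (0.138 and 0.0331) with DOX, and these 4 passed only with the block. TFPI2 differed by -2.06 with flow (0.0932 and 0.00954). Of the markers of other cell types, 1 had a name, the smooth muscle gene SMTN, which differed by 0.67 with DOX (0.0948, and 0.0445 with the block). The venous, cholesterol synthesis, hypoxia, mitochondrially encoded, fibroblast, leukocyte, epithelial, erythroid and lymphatic lists had no named member.

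Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many probe sets, with 242, 351 and 1436 called against a highest of 0 in the others, including the other splits that parted all 3 pairs. At an unadjusted p under 0.05 in limma the other splits had 511 to 1867, 907 to 5378 and 1092 to 5229 probe sets, against 3895, 6471 and 7601 for the real ones. The other splits mix the real groups, so a real difference widens their spread and lowers their calls. Their counts are thus no measure of what arrays without a difference would give.

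DOX replicate 2 lay nearest the flow arrays, with r = 0.989 to its same-number flow array, against 0.964 and 0.979 for DOX replicates 1 and 3. An untreated or mislabelled culture may look so, but on the 500 probe sets most changed in the other 2 pairs the median signed log2 change in pair 2 was 0.73, with 91.2% in the same direction, which argues against it. The corresponding medians were 1.56 and 1.38 for pairs 1 and 3. Each pair was scored on its own 500 probe sets. On these the median size of the mean change in the other 2 pairs was 1.42, 1.88 and 1.6 for pairs 1, 2 and 3. Pair 2 thus changed the same way but by less than the other pairs. For a uniformly weaker drug effect the p53 list was read, whose median change was 1.49 in pair 2, against 0.77 and 1.47 in pairs 1 and 3. That list cannot decide it, because its members were named for a DOX change on arrays that include pair 2. Over all probe sets the SD of DOX minus flow was 0.317 in pair 2, against 0.554 and 0.429 in pairs 1 and 3. Some lists had smaller medians in pair 2, the flow-induced list with -1.12 against -3.04 and -2.95 in pairs 1 and 3. Endothelial identity had -0.59 against -1.52 and -1.34, Notch -1.13 against -2.27 and -1.34, and the histones 0.61 against 1.83 and 2.04. The G2 and M phase list changed most in pair 2, with -1.02 against -0.705 and -0.505. Recombination (-0.98 against -1.12 and -0.7) and replication (-0.72 against -0.88 and 0.08) lay between the other pairs. So did immediate early (2.01 against 1.37 and 2.96) and flow-repressed genes (0.765 against 0.845 and 0.255). Members of these lists too were named for a DOX change on arrays that include pair 2. A weaker drug effect and a difference that touches some gene groups and not others both stay open.

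Genes that rose with flow and fell with DOX may owe part of this to the flow arrays shared by both comparisons. With the spread of the blocked fit, which keeps the pairing, the covariance of the changes differed from the simulated one by -0.00421 and lay below the simulated range of -0.0131 to -0.0117. With that of the fit without block, which ignores the pairing, it differed by 0.00215 and lay above the range of -0.0199 to -0.0175. Between flow changes in one pair and DOX changes in another, which share no array, the median covariance over 6 combinations was -0.0043, with 5 below 0 and a range from -0.0262 to 0.00681. Both simulations used a spread pooled over the 3 groups, although DOX arrays correlated less with each other than flow arrays did. The shared arrays act through the spread of the flow arrays, so both simulated covariances may overstate their part. The simulations also drew probe sets independently, so their ranges leave out correlation between probe sets. The combinations without a shared array fall on both sides of 0. A shared effect and the shared arrays thus cannot be told apart here.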
